A study of Mus musculus with 18 samples.

How the data were processed

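RNA from flash-frozen livers of 18 female mice (6 old ouabain, 6 old vehicle, 6 young) was sequenced, with 1 library per animal by the titles. The design given with the series describes 16 old mice, and how the 12 old animals analysed here were chosen is not given in the sources used here. Per the submitters' processing notes, reads were aligned to the mouse build mm9 with TopHat2 2.0.11 and counted per gene with featureCounts. The strand setting, the annotation release and the treatment of reads shared between genes are not given in the sources used here, so antisense, overlapping and closely related genes cannot be told apart with certainty. The authors deposited 1 table of raw read counts for 37620 Ensembl genes in the 18 libraries, not normalized, whose columns carry the sample titles. Symbols were found for 32897 identifiers in a table of gene names, and the other 4723 hold 1.46% of the counts. The reference annotation at hand is of another build, so no coordinates are given.

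Library totals were 4201251 to 11113307 counts. A count of 0 in a library allows up to 3 counts, which is 0.27 to 0.714 CPM, and such limits cover counting error only. Between libraries of a group the chi-square per gene was 5.31 to 58.1, where sampling noise gives 1, so no library appeared to be deposited more than once. The labels give no batch or date.

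Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept with edgeR's filter for the 3 groups (minimum count 10), which left 14226 genes, and scaled with TMM factors. All 18 libraries entered 1 fit, since the groups are livers of one series, and the pairs of groups were compared with the quasi-likelihood F-test (robust dispersion, two-sided, Benjamini-Hochberg adjusted p below 0.05). The biological coefficient of variation was 0.183. Standard errors of log2 fold changes are approximate, as the fold change divided by the square root of F. CPM values are scaled by TMM and given as mean ± SD of 6 libraries, and principal components used log2 CPM with a prior count of 2.

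Before the data were examined, 47 gene lists for liver functions, cell types and senescence were written down, from general knowledge. They were tested with camera on limma 3.58.1 voom values with a preset correlation of 0.01, adjusted over the lists of a comparison. CDK inhibitors and pancreas markers had fewer than 5 measured genes and were not tested. In the 4 CDK inhibitors measured, 3 rose with age. The alternatives were an estimated correlation, fry, quality weights, only the 12 libraries compared, the replicate block and leaving out each library. fry tests whether the genes of a list move on balance in one direction and does not compare them with other genes.

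The genes named were also fixed beforehand. Per comparison they are the 8 largest rises and 8 largest falls among genes past the threshold with a mean log2 CPM of at least 2 and at least 5 of 6 libraries of each group beyond the median of the other, without predicted genes (Gm and Rik names), Mup, immunoglobulin and T cell receptor segments and pseudogenes. To these were added up to 3 members of each list that passed and up to 2 of each list that did not, and 5 genes per direction with opposite calls. Cdkn1a, Cdkn2a, Pmaip1, Gdf15, Lmnb1, Mki67 and Atp1b1 were named whatever their values. Some genes that these rules select are not reported here.

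Other settings planned for the counts of genes were size factors by relative log expression, no filter, a filter at 1 CPM in 6 libraries, DESeq2 1.42.0, limma voom with and without quality weights, only the 12 libraries compared, a replicate block, 1 surrogate variable from sva 3.50.0, and leaving out each library. Dropping old vehicle replicate 4 with old ouabain replicate 5, and thinning all libraries to the shallowest, were chosen after seeing the data. The fit was tested on simulated counts for the 14226 genes with real means, dispersions and library sizes. For old ouabain versus old vehicle, it recovered 82% of 100 genes changed 2-fold and 97% of 100 changed 4-fold, with 4.6% false calls. In the same counts the list test found 5 of 5 shifted lists and none of 35 others. The simulated genes varied independently, so this does not test false calls among genes that vary together. In random regroupings of the real ouabain and vehicle libraries it called a median of 17 lists.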

Results

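Messenger RNA was measured by sequencing in the livers of 18 female mice. There were 6 old mice given ouabain, 6 old mice given vehicle and 6 young mice. Ouabain is a cardiac glycoside that blocks the sodium and potassium pump (Na,K-ATPase) and kills some senescent cells in culture. The old mice were 24 months of age when sampled and the young mice 7 weeks. Ouabain was given at 1 mg/kg in rounds of 4 treatments a week with 2 weeks of rest between rounds, over 12 weeks, and livers were taken 3 days after the last round. The labels describe the young mice without a treatment, so age and handling differ together in every comparison with them. Library totals ran from 4201251 counts (old ouabain replicate 5) to 11113307 counts (young replicate 2), and the next shallowest library had 7527846 counts. Of 37620 genes in the table, 14226 had enough counts to be tested. The first principal component of log2 CPM held 31.5% of the variance and placed young livers at 17.7 to 43.0, ouabain livers at -14.7 to 10.98 and vehicle livers at -45.1 to -10.7.

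**Figure D1:**
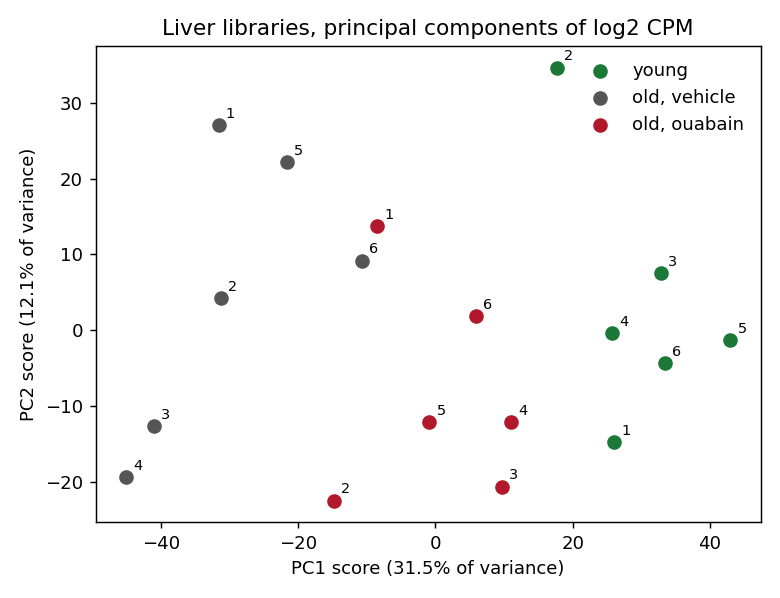
Principal components of log2 CPM for the 18 liver libraries, with PC1 on the x axis and PC2 on the y axis (scores, percent of variance in the labels); each point is a library, coloured by group and numbered by replicate. Young and old vehicle livers lie at opposite ends of PC1, and ouabain livers lie between them, overlapping the vehicle livers.

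The first comparison asks what ouabain changed in the old liver. The largest rise among the genes named here was in Slco1a1 (ENSMUSG00000041698), an organic anion transporter of hepatocytes that is expressed more in male than in female liver. It was at 0.782 ± 0.461 CPM in vehicle livers and 66.5 ± 20.5 CPM in ouabain livers (SD, n = 6 each), a log2 fold change of 6.38 (SE 0.52, edgeR adjusted p = 1.86e-05), with all 6 ouabain libraries above all 6 vehicle libraries. Genes of the macrophage lineage and of NF-kB signalling fell, among them Itgax (CD11c), from 4.31 ± 1.60 to 1.83 ± 0.302 CPM (log2 fold change -1.25, SE 0.24, adjusted p = 0.0138, lower in 6 of 6). In all, 262 genes changed at an edgeR adjusted p below 0.05, of which 141 rose and 121 fell. Only 68 of them changed more than 2-fold.

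Male-biased liver genes rose together. Of 26 measured, 11 rose and none fell, or 16 and none when adjusted over the list alone, with a median log2 fold change of 0.82 (camera adjusted p = 5.87e-15, adjusted p = 0.0697 with an estimated correlation, fry adjusted p = 0.000691). Besides Slco1a1 they included Nudt7, a peroxisomal enzyme that cleaves coenzyme A (71.9 ± 17.3 to 213 ± 50.9 CPM, log2 fold change 1.57, SE 0.23, adjusted p = 0.00405). The cytochromes P450 Cyp2u1 (log2 fold change 1.92, adjusted p = 0.00405) and Cyp2d9 (1.37, adjusted p = 0.00462) were in the same list. Hsd3b5, a male-biased steroid dehydrogenase, rose by a fitted log2 fold change of 5.75 (SE 1.19, adjusted p = 0.0245), but its vehicle value rests on 6 counts over all 6 libraries, so that fold is imprecise. Of 27 female-biased genes, 1 fell and the list did not pass (adjusted p = 0.0799), though it did without old vehicle replicate 4 (0.0271) or 5 (0.0297). Slco1a1, Cyp2d9 and the carboxylesterases have close paralogs, and how the authors' counting divided shared reads is not given in the sources used here.

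Other genes that rose were the carboxylesterases Ces3a (log2 fold change 1.52, adjusted p = 0.0138) and Ces3b (1.33, adjusted p = 0.00256), the lectin-like gene Clec2h (3.50, adjusted p = 0.0129), Nrep (2.21, adjusted p = 0.00963), and the prostaglandin D synthase Ptgds (2.13, adjusted p = 0.01). Carmil1, a regulator of actin capping, rose 2.84-fold (adjusted p = 0.0446). Among metabolic pathways, the respiratory chain list rose by a small amount, with 5 of 76 genes up and none down, 12 and none adjusted over the list alone, and a median log2 fold change of 0.17 (camera adjusted p = 1.51e-11, adjusted p = 0.534 with an estimated correlation). Uqcrc1, a core subunit of complex III, went from 174 ± 17.4 to 227 ± 12.4 CPM (log2 fold change 0.38, adjusted p = 0.0138). The 13 mitochondrially encoded genes went the other way as a list, with a median log2 fold change of -0.18 and none past the threshold, also adjusted over the list alone (camera adjusted p = 0.0165, adjusted p = 0.566 with an estimated correlation). That call ended without old ouabain replicate 4 (0.0664) or old vehicle replicate 2 (0.0655), 3 (0.0530) or 6 (0.0552). In the fatty acid synthesis list 1 of 24 genes rose, Srebf1, the transcription factor that drives lipogenic genes (0.72, adjusted p = 0.0417). Adjusted over the list alone 5 rose, and the list had a camera adjusted p of 0.00122, with adjusted p = 0.534 for an estimated correlation. Cyp2f2, a periportal hepatocyte gene, rose by 0.78 on the log2 scale (adjusted p = 0.0369). Endoplasmic reticulum chaperones and heat shock genes were also higher as lists by camera, in 18 and 17 of 18 fits without 1 library. A camera p as small came from 26 and 14 of 100 groupings of the libraries, the real one included. Neither list passed with an estimated correlation.

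Several immune and inflammatory lists fell, while B cell, plasma cell, dendritic cell and acute phase lists did not pass (camera adjusted p = 0.693, 0.108, 0.222 and 0.0805). Each of these passed as lower without some library: B cell without old ouabain replicate 2 (0.0178), plasma cell without old ouabain replicate 6 (0.0392), dendritic cell without old vehicle replicate 6 (0.0365), and acute phase without old ouabain replicate 4 (0.00279) or old vehicle replicate 1 (0.0474), 2 (0.0378) or 6 (0.0136). Of 20 markers of monocyte-derived macrophages, 4 fell and none rose (15 and none adjusted over the list alone), with a median log2 fold change of -0.91 (camera adjusted p = 4.51e-09, adjusted p = 0.243 with an estimated correlation, fry adjusted p = 0.0136). The 4 were Itgax, the chemokine receptor Ccr2 (-1.22, adjusted p = 0.0348), Ms4a7 (-1.18, adjusted p = 0.0296) and Ms4a6c (-0.95, adjusted p = 0.0327). Of 21 NF-kB feedback and target genes 3 fell, or 9 adjusted over the list alone (camera adjusted p = 8.1e-06, adjusted p = 0.347 with an estimated correlation). They were the inhibitor Tnfaip3 (-1.02, adjusted p = 0.0161), Nfkbiz (-0.91, adjusted p = 0.0262) and the monocyte chemokine Ccl2 (-1.61, adjusted p = 0.0285). Trim30a was the 1 gene of 46 interferon-stimulated genes that fell (-0.66, adjusted p = 0.0424), and Nr4a1 the 1 of 22 immediate early genes (-1.47, adjusted p = 0.0414). Adjusted over the list alone these were 1 and 8, with camera adjusted p of 3.56e-05 and 0.00445 and an adjusted p of 0.534 for both with an estimated correlation. Trim30a and Nr4a1 each passed in only 7 of 18 fits without 1 library and under 5 of 11 other settings. Other large falls were in the leukocyte genes Plek (-1.23, adjusted p = 0.0321), Clec4a3 (-1.24, adjusted p = 0.0404) and Pla2g7 (-1.23, adjusted p = 0.0369). The matricellular gene Ccn2 (-1.91, adjusted p = 0.0285), Srrm4 (-1.34, adjusted p = 0.0285), Atp11a (-1.21, adjusted p = 0.043) and the uncharacterised transcript AI662270 (-1.19, adjusted p = 0.0452) fell as well. T cell, natural killer cell, neutrophil, Kupffer cell and MHC class II lists had lower medians (-0.90, -0.87, -1.09, -0.57 and -0.71 on the log2 scale) with no single member past the threshold. Their camera adjusted p were 0.0121, 0.0168, 0.0105, 0.0188 and 0.000605, and with an estimated correlation 0.664 for Kupffer cells and 0.534 for the others. The Kupffer cell call ended without old vehicle replicate 4 (adjusted p = 0.315), 3 (0.148) or 2 (0.0655) and without old ouabain replicate 4 (0.0695) or 3 (0.0633). The T cell call ended without old vehicle replicate 1 (0.0664), the natural killer cell call without old vehicle replicate 3 (0.0524), and the neutrophil call without old vehicle replicate 3 (0.0524) or 4 (0.0592) or old ouabain replicate 1 (0.0602).

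The list of secreted factors of senescent cells had 3 genes that fell and 1 that rose among 37 (7 and 1 adjusted over the list alone), with a camera adjusted p of 0.00081, and adjusted p = 0.459 with an estimated correlation. A camera p as small came from 10 of 100 groupings of the libraries, the real one included. The list shares Ccl2 and other chemokine and cytokine genes with the NF-kB list, so these lists are not independent. The tumour necrosis factor receptor Tnfrsf1b fell from 46.6 ± 8.60 to 28.5 ± 1.24 CPM (log2 fold change -0.71, SE 0.12, adjusted p = 0.00509, lower in 6 of 6). The mean log2 CPM of the p53 target list was 3.37 to 3.48 in ouabain, 3.49 to 3.72 in vehicle and 3.14 to 3.36 in young libraries. For ouabain versus vehicle, 9 of 100 groupings gave that list a camera p as small as the real one, which is included. The senescence and proliferation genes fixed beforehand did not pass. Cdkn1a, encoding the cell cycle inhibitor p21, was at 7.60 ± 6.00 CPM in vehicle and 3.24 ± 1.37 CPM in ouabain livers (log2 fold change -1.17, SE 0.47, adjusted p = 0.18). Its vehicle values ran from 1.23 CPM in replicate 5 (12 counts) to 18.7 CPM in replicate 4 (195 counts). The pro-apoptotic gene Pmaip1 differed by -0.82 (SE 0.35, adjusted p = 0.196) and Mki67 by -1.01 (SE 0.46, adjusted p = 0.228). Both vehicle means are raised by replicate 4, with Pmaip1 at 4.99 CPM (others 1.21 to 2.03) and Mki67 at 27.5 CPM (others 3.82 to 8.71). Gdf15 differed by 0.20 (SE 0.17, adjusted p = 0.526) and Lmnb1 by 0.01 (SE 0.17, adjusted p = 0.983). Cdkn2a, encoding p16, had 0 to 28 counts in a library and was too low to test, with 48 counts over the vehicle libraries and 40 over the ouabain libraries, of which 28 were in replicate 2. The pump subunit gene Atp1b1 (0.26, SE 0.12, adjusted p = 0.221) did not pass, nor did any of the 7 Na,K-ATPase genes measured.

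In this comparison 22 of 45 lists passed camera with a preset correlation, 0 with an estimated correlation and 4 by fry. The number of genes changed depended on single libraries, from 69 without old ouabain replicate 6 to 642 without old vehicle replicate 6. Carmil1 passed in only 5 of 18 fits without 1 library, Atp11a and AI662270 in 6, and Clec4a3 and Srebf1 in 8. The number of genes was 85 without old vehicle replicate 4 and old ouabain replicate 5, 133 with all libraries thinned to the shallowest, 53 with 1 surrogate variable, 599 with DESeq2 and 1002 with quality weights.

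**Figure D2:**
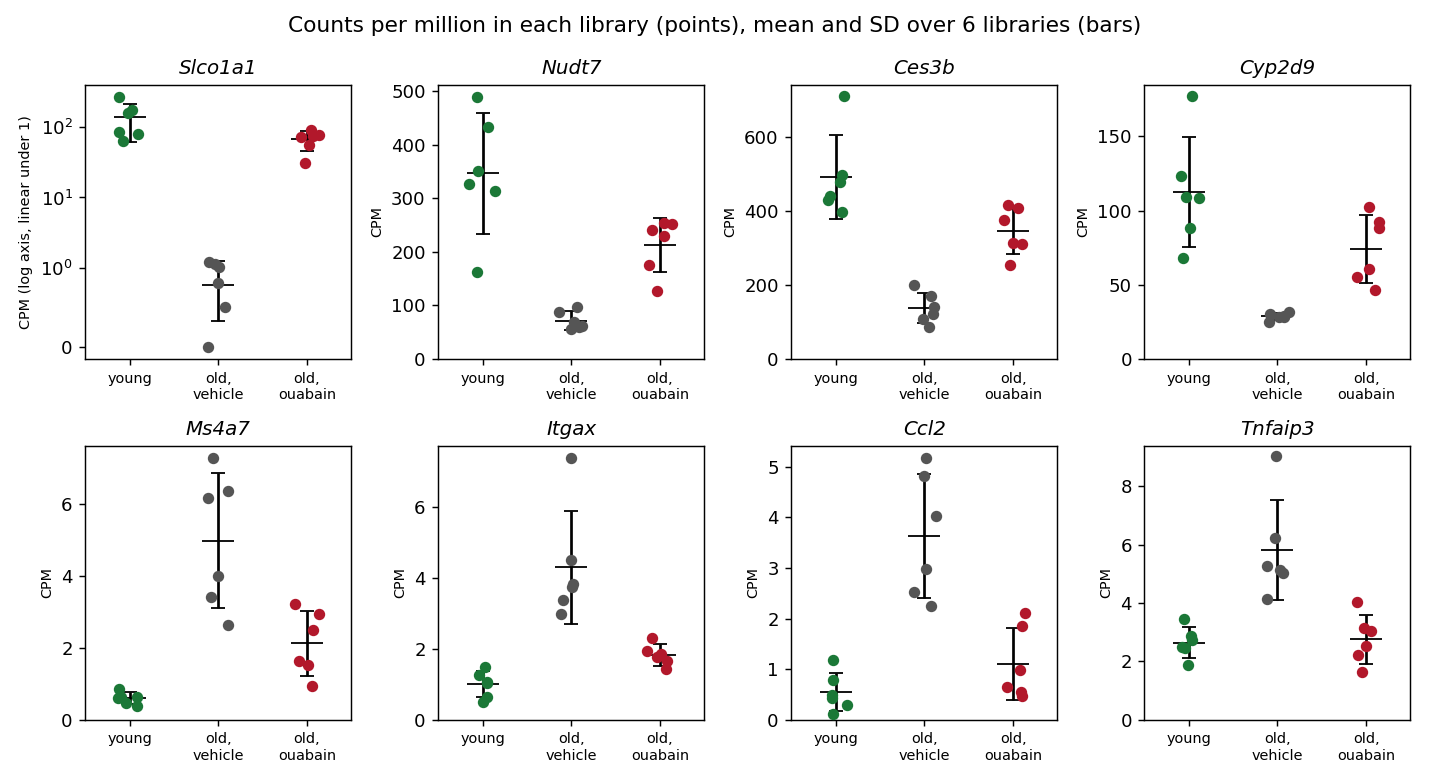
CPM (y axis; logarithmic above 1 and linear below for Slco1a1, linear for the rest) of 4 genes that rose with ouabain (upper row) and 4 that fell (lower row), in young, old vehicle and old ouabain livers. Points are libraries, and the horizontal mark and bar give the mean and SD of 6 libraries. All 6 ouabain libraries lie above all 6 vehicle libraries for the upper genes. For the lower genes the ouabain mean in CPM lies nearer to young than to vehicle livers. For Ms4a7 the fold change is nonetheless larger from young than from vehicle livers.

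The comparison of old vehicle with young livers asks what differs between 24 months and 7 weeks of age. No age between these was sampled, so changes early in life cannot be told apart from late ones. Old livers had far more transcripts of immunoglobulins, antigen presentation and macrophages, more transcripts of some p53 targets, and fewer transcripts of endoplasmic reticulum chaperones and male-biased genes. With an estimated correlation the plasma cell, macrophage and male-biased lists passed (adjusted p = 0.0479 each) and the MHC class II, p53 and chaperone lists did not (0.0728 each). Ighm, of the plasma cell list, rose from 5.75 ± 1.28 to 90.7 ± 34.8 CPM (log2 fold change 3.98, SE 0.37, adjusted p = 5.32e-06, higher in 6 of 6), and Slco1a1 fell from 137 ± 75.9 to 0.782 ± 0.461 CPM (-7.42, SE 0.52, adjusted p = 4.13e-07, lower in 6 of 6). In all 2733 genes changed, 1549 up and 1184 down, and 904 changed more than 2-fold.

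Plasma cell markers had 10 genes that rose and 2 that fell among 15, or 12 and 2 adjusted over the list alone (camera adjusted p = 2.86e-05, adjusted p = 0.0479 with an estimated correlation). They included Igkc (log2 fold change 4.12, adjusted p = 1.04e-05) and Jchain (3.36, adjusted p = 0.000216). One of those that fell was Derl3 (-3.86, adjusted p = 0.000195), a component of the degradation machinery of the endoplasmic reticulum. It is also in the chaperone list, and its young mean is raised by young replicate 1 (34.4 CPM, others 3.84 to 14.2). B cell markers also passed as a list in 18 of 18 fits without 1 library (camera adjusted p 9.36e-06 to 0.00724), though not with an estimated correlation. A camera p as small came from 20 of 100 groupings of the libraries. The rise of immunoglobulin genes thus cannot be placed in plasma cells alone. Monocyte-derived macrophage markers had 18 genes that rose and 2 that fell among 20, the same adjusted over the list alone (camera adjusted p = 1.77e-11, adjusted p = 0.0479 with an estimated correlation). Itgax was at 2.06, Ms4a7 at 3.04 and the lipid receptor Trem2 at 3.17 on the log2 scale (adjusted p = 2.21e-05, 3.89e-06 and 0.000179). All 10 MHC class II genes rose, also adjusted over the list alone (camera adjusted p = 1.95e-09, adjusted p = 0.0728 with an estimated correlation). H2-Aa went from 20.8 ± 4.83 to 99.7 ± 54.9 CPM (2.26, adjusted p = 0.000215). The neutrophil gene S100a8 rose by 2.81 (adjusted p = 0.000775), in a list with 9 of 12 genes up, and 9 adjusted over the list alone (camera adjusted p = 2.62e-05, adjusted p = 0.293 with an estimated correlation).

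Of 37 secreted factors of senescent cells 15 rose and 1 fell, or 19 and 4 adjusted over the list alone (camera adjusted p = 0.000109, adjusted p = 0.17 with an estimated correlation). Ccl5 was at 3.01, Ccl2 at 2.65 and Cxcl13 at 3.25 on the log2 scale (adjusted p = 2.93e-05, 0.000148 and 0.0136). Of 26 p53 targets 8 rose and none fell, the same adjusted over the list alone (camera adjusted p = 0.0168, adjusted p = 0.0728 with an estimated correlation). They included Cdkn1a, at 1.53 ± 0.998 CPM in young and 7.60 ± 6.00 CPM in old vehicle livers (log2 fold change 2.31, SE 0.51, adjusted p = 0.0047), Pmaip1 (1.55, adjusted p = 0.00538) and Phlda3 (1.58, adjusted p = 0.000235). Cdkn1a varied widely among vehicle livers, from 1.23 CPM, below the young mean, to 18.7 CPM in replicate 4, which raises its fold. It still passed in 18 of 18 fits without 1 library. Cdkn2a, not tested, had 4 counts over the young libraries (0.0708 ± 0.110 CPM) and 48 over the old vehicle libraries (0.786 ± 0.477 CPM). All 6 vehicle libraries were above all young ones, but by as little as 3 counts against 2, which is within counting error. Mki67, a gene of dividing cells, rose by 1.81 (adjusted p = 0.0137) in a cell cycle list with 4 of 39 genes up, or 2 adjusted over the list alone (camera adjusted p = 0.015, adjusted p = 0.669 with an estimated correlation). The cell cycle call ended without old vehicle replicate 4 (adjusted p = 0.524) or young replicate 3 (0.0507). In that vehicle replicate Mki67 was at 27.5 CPM (others 3.82 to 8.71), which raises its fold. Mki67 still passed in 18 of 18 fits without 1 library. Among the pump genes, Fxyd5 rose (1.80, adjusted p = 9.62e-06) and Atp1b1 fell (-0.39, adjusted p = 0.0232). Atp1b1 missed the threshold in the fit of only these groups (adjusted p = 0.0603), without old vehicle replicate 4 together with old ouabain replicate 5 (0.0639), and without old vehicle replicate 3 (0.0607) or 4 (0.0527) alone. Gdf15 (0.40, adjusted p = 0.109) and Lmnb1 (0.17, adjusted p = 0.51) did not pass, though Gdf15 did without young replicate 1 (0.55, adjusted p = 0.0186).

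Of the secretory pathway, 18 of 26 endoplasmic reticulum chaperone genes fell and none rose, or 20 and none adjusted over the list alone (median log2 fold change -0.54, camera adjusted p = 1.27e-12, adjusted p = 0.0728 with an estimated correlation). Dnajb11 went from 145 ± 25.8 to 85.4 ± 14.2 CPM (-0.76, adjusted p = 0.000255). Of 26 male-biased genes 17 fell and 1 rose, or 17 and 2 adjusted over the list alone (camera adjusted p = 1.27e-12, adjusted p = 0.0479 with an estimated correlation). Of 27 female-biased genes 15 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 1.33e-06, adjusted p = 0.0728 with an estimated correlation). Female-biased genes that rose were A1bg (203 ± 135 to 3755 ± 1739 CPM, 4.21, adjusted p = 0.000238), the sulfotransferases Sult2a1 (2.39, adjusted p = 2.98e-05) and Sult1e1 (7.60, adjusted p = 0.0015), and Cyp3a44 (2.18, adjusted p = 1.71e-05). Sult1e1 had 18 counts over the 6 young libraries, and its old mean rests on 1 library. Outside the lists, Sult2a3 (5.49, adjusted p = 5.29e-07) and the adenylate cyclase Adcy1 (5.83, adjusted p = 6.72e-05) rose. Other large falls were in Hsd3b5 (-6.32, adjusted p = 0.00122), Clec2h (-4.13, adjusted p = 0.000238) and Cib3 (-3.14, adjusted p = 0.0142). The receptor Adgrf1 (-3.08, adjusted p = 0.00382), Nrep (-2.84, adjusted p = 0.000117) and Ptgds (-2.73, adjusted p = 9.86e-05) fell as well. Hsd3b5 had 6 counts over the vehicle libraries and was high in young replicate 5 (28.9 CPM, others 0.639 to 9.60), so its fold is imprecise. Clec2h was high in young replicate 2 (25.2 CPM, others 5.67 to 7.55), as was Cib3 (28.5 CPM, others 4.49 to 8.22). Cib3 was also high in old vehicle replicate 5 (4.51 CPM, others 0.0959 to 1.41), and Adgrf1 ran from 0 to 3.08 CPM in vehicle livers. Of 45 lists, 22 passed camera, 3 of them with an estimated correlation, and 23 passed fry.

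The comparison of ouabain-treated old livers with young livers asks how far the treated livers still differed from young ones. Some immunoglobulin, MHC class II, macrophage and female-biased genes were still higher and a few chaperone genes lower, but no list passed with an estimated correlation. No male-biased gene was past the threshold. Ighm was at 71.8 ± 26.8 CPM against 5.75 ± 1.28 CPM in young livers (log2 fold change 3.64, SE 0.37, adjusted p = 9.21e-05, higher in 6 of 6). In all 160 genes changed, 105 up and 55 down, and 147 of them had also changed in the same direction in old vehicle livers (2586 genes passed only with vehicle). Both comparisons use the same young libraries, which makes them share genes, and how many was not simulated. Passing in one and not in the other is not a difference between them, and the direct test is that of ouabain against vehicle.

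Plasma cell markers had 5 of 15 genes up, or 8 up and 2 down adjusted over the list alone (camera adjusted p = 5.23e-06, adjusted p = 0.0535 with an estimated correlation). Igkc was at 3.50 and Jchain at 2.65 on the log2 scale (adjusted p = 0.000658 and 0.0179). B cell markers passed as a list here too, in 18 of 18 fits without 1 library (camera adjusted p 1.1e-06 to 0.00136). MHC class II had 2 of 10 up, H2-Aa (1.41, adjusted p = 0.0431) and H2-Eb1 (1.46, adjusted p = 0.0431). Adjusted over the list alone 9 rose, with a camera adjusted p of 7.76e-09 and adjusted p = 0.159 with an estimated correlation. Macrophage markers had 3 up and 1 down of 20, or 13 and 1 adjusted over the list alone (camera adjusted p = 5.29e-07, adjusted p = 0.186 with an estimated correlation). Those up included Trem2 (2.17, adjusted p = 0.0371) and Ms4a7 (1.86, adjusted p = 0.0119). The chemokine Ccl5 rose by 1.98 (adjusted p = 0.0179) and Phlda3 by 1.17 (adjusted p = 0.0308). The p53 target list did not pass camera, though only 1 of 100 groupings, the real one, gave a camera p as small. Cdkn1a (1.14, SE 0.55, adjusted p = 0.308), Pmaip1 (0.73, adjusted p = 0.367), Mki67 (0.81, adjusted p = 0.446), Gdf15 (0.60, adjusted p = 0.0929) and Lmnb1 (0.18, adjusted p = 0.628) did not pass, though Gdf15 did without young replicate 1 (0.74, adjusted p = 0.0165) and with quality weights (0.69, adjusted p = 0.0175). Neither did the pump gene Atp1b1 (-0.13, adjusted p = 0.619). Fxyd5 rose by 1.15 (adjusted p = 0.0117).

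Female-biased genes had 8 of 27 up, or 13 adjusted over the list alone (camera adjusted p = 4.5e-09, adjusted p = 0.0535 with an estimated correlation). A1bg was at 3.36, Sult2a1 at 1.77 and Cyp2a4 at 1.20 on the log2 scale (adjusted p = 0.0133, 0.00635 and 0.00608), and Cyp3a44 rose 2.83-fold (adjusted p = 0.00662). Male-biased genes had 0 of 26 past the threshold and 4 lower adjusted over the list alone (median -0.44, camera adjusted p = 0.0009, adjusted p = 0.378 with an estimated correlation). Slco1a1 differed by -1.04 (SE 0.34, adjusted p = 0.15). Chaperones had 3 of 26 down, or 17 adjusted over the list alone (camera adjusted p = 6.18e-14, adjusted p = 0.159 with an estimated correlation). Among them were Dnajb11 (-0.54, adjusted p = 0.0325) and Dnajc3 (-0.47, adjusted p = 0.023). Further rises were in Sult2a3 (4.98, adjusted p = 8.85e-06), Adcy1 (3.99, adjusted p = 0.0188) and Id1, a target of bone morphogenetic protein signalling (2.07, adjusted p = 0.0284). The falls were smaller, and included Nucb2 (-1.02, adjusted p = 0.0353), Bach2 (-0.89, adjusted p = 0.0399), Ralgps1 (-0.73, adjusted p = 0.0204), Grb10 (-0.65, adjusted p = 0.0431), Atp8b1 (-0.64, adjusted p = 0.0181), Mid2 (-0.63, adjusted p = 0.0287), Plcb1 (-0.62, adjusted p = 0.0286) and Fermt2 (-0.61, adjusted p = 0.0181). Of 45 lists, 23 passed camera, 0 with an estimated correlation and 7 by fry. The number of genes changed ran from 51 without old ouabain replicate 2 to 612 without young replicate 1. Grb10 passed in only 6 of 18 such fits, H2-Eb1 in 7, and H2-Aa and Bach2 in 9. The number of genes was 78 thinned to the shallowest library, 103 without old vehicle replicate 4 and old ouabain replicate 5, 333 in the fit of only these groups, 466 with DESeq2 and 532 with quality weights.

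**Figure D3:**
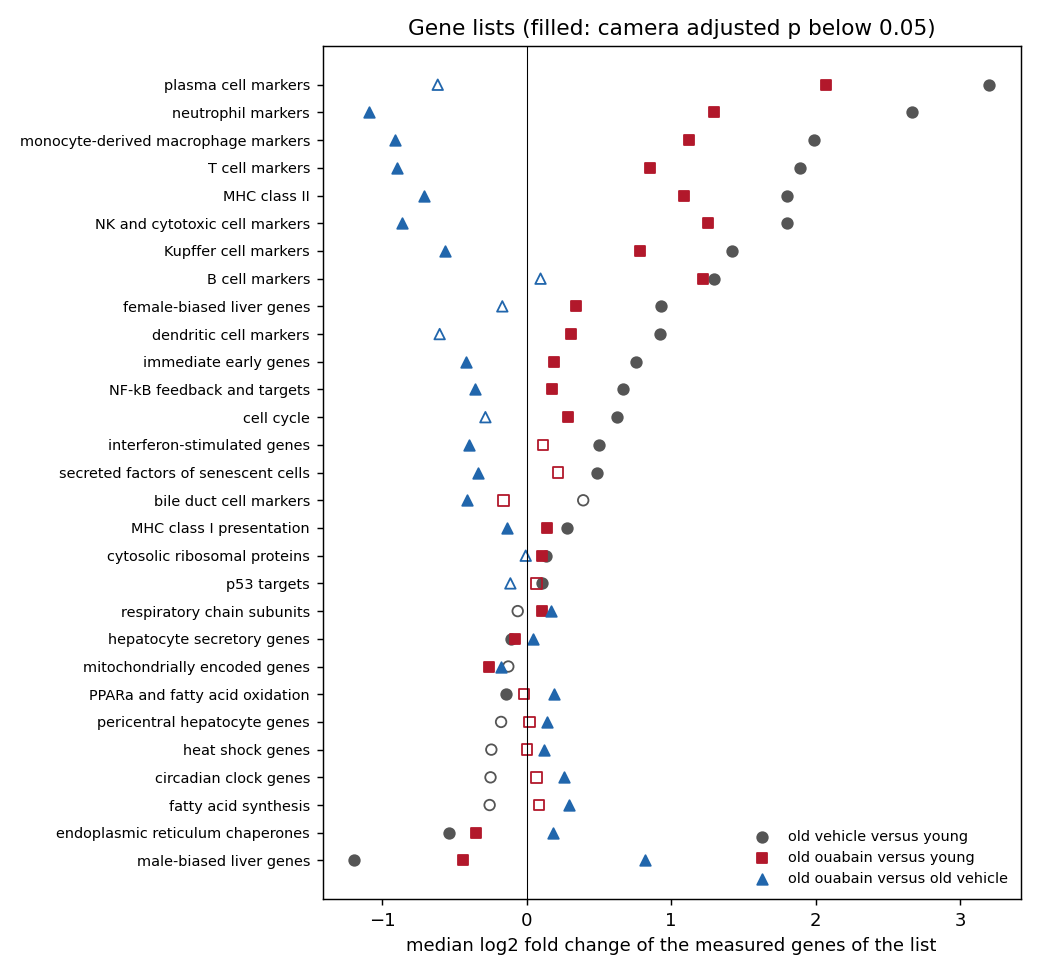
Median log2 fold change (x axis) of the measured genes of each list (y axis) that passed camera in old vehicle versus young or in old ouabain versus old vehicle. Circles are old vehicle versus young, squares old ouabain versus young and triangles old ouabain versus old vehicle, filled where the camera adjusted p was below 0.05; for macrophage markers the medians are 1.99, 1.12 and -0.91.

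Set side by side, 231 genes passed in both the age and the ouabain comparison, and all 231 moved in opposite directions, with 0 in the same direction. Of these, 106 rose with age and fell with ouabain and 125 fell with age and rose with ouabain, while 31 genes passed for ouabain and not for age. Among well-measured genes, those with small adjusted p in both included Nat8f1, an N-acetyltransferase family gene (192 ± 24.4 CPM in young, 93.6 ± 9.02 in vehicle and 155 ± 10.8 in ouabain livers), the receptor kinase gene Epha1 (45.6 ± 2.55, 24.7 ± 2.69 and 39.9 ± 6.16 CPM), Ces3b, Nudt7 and Slco1a1. In the other direction were Fam126a (14.9 ± 1.29, 29.5 ± 2.81 and 20.4 ± 1.91 CPM), Mbnl2 (25.8 ± 2.13, 36.9 ± 4.47 and 25.1 ± 2.52 CPM), Tifa, an adaptor of NF-kB signalling (18.3 ± 3.78, 27.6 ± 4.49 and 16.2 ± 1.52 CPM), Asah1, which encodes acid ceramidase (37.1 ± 4.38, 49.7 ± 4.40 and 34.6 ± 3.39 CPM), and Tnfrsf1b.

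Both effects use the same vehicle libraries, with opposite signs, so chance alone makes them go in opposite directions. Across genes, which are not independent replicates, Pearson's r between the effects was -0.77 and the covariance -0.162. In 20 simulations with no effect the medians were -0.49 and -0.0221, so the covariance was lower by 0.14. The simulated genes varied independently, with the same spread in all groups. These medians therefore need not hold for real genes that vary together. Lists that are independent would share 24.9 genes in opposite directions and 25.4 in the same direction. With the vehicle libraries split 3 and 3, so that each effect had its own, the median over 20 splits was 38 genes in opposite directions (12 to 291) and 0 in the same direction (at most 1), with a median r of -0.57 and a median covariance of -0.134.

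**Figure D4:**
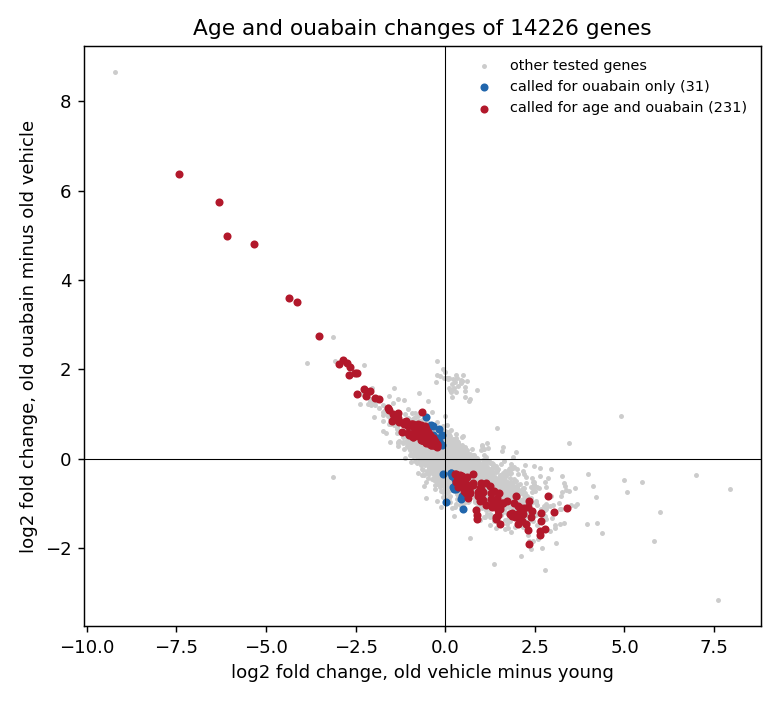
Log2 fold change of old ouabain minus old vehicle (y axis) against that of old vehicle minus young (x axis) for 14226 tested genes, which share the vehicle libraries. Red points are the 231 genes that passed in both comparisons, blue points the 31 that passed for ouabain and not for age, and grey points the other genes; all red points lie at the upper left and lower right.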

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

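The tests of library depth, of immune cells for the genes that fell with age, of Y-linked genes, of single libraries for both lists, of shares of hepatocytes of residual blood, and the regroupings of young libraries for opposite calls were chosen or given their limits only after the results were seen. For normally distributed values chance sets about 1 in 20 groups of 6 apart by the gap rule used here. The rule set 28 of 240 groups apart, or 11.7%. It was applied mostly to untransformed CPM, for which that chance rate need not hold. The gap between the extreme library and its nearest neighbour was large against the range of its group in the following cases, given as CPM.

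In young replicate 2, Clec2h was at 25.2, Srrm4 at 10.2, Ccr2 at 2.92, Mki67 at 5.75, Cib3 at 28.5 and Id1 at 9.59, each above the other young livers. In young replicate 5, Hsd3b5 was at 28.9, Ces3a at 1243 and Ces3b at 709, above the others, and Trim30a at 8.54, below them. In young replicate 1, Sult1e1 was at 0.685, Derl3 at 34.4 and Dnajb11 at 195.

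In old vehicle replicate 4, Mki67 was at 27.5 (others 3.82 to 8.71) and Pmaip1 at 4.99 (others 1.21 to 2.03). In old vehicle replicate 1, Sult1e1 was at 308.5 (others 9.02 to 17.7) and Srrm4 at 23.8. Itgax at 7.39 and Phlda3 at 3.85 were high in old vehicle replicate 3, and Cib3 at 4.51 and Fermt2 at 61.0 in old vehicle replicate 5. In old ouabain replicate 2, Cdkn2a was at 2.61 and Fxyd5 at 10.98, above the others, and Atp1b1 at 51.3, Atp8b1 at 15.7 and Dnajc3 at 164 were below them. Cyp2u1 was at 6.50 in old ouabain replicate 5 and Jchain at 13.9 in old ouabain replicate 6.

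The first pattern weighed is that genes called for both age and ouabain moved in opposite directions. Sharing of the vehicle libraries is argued against as the whole reason, since with split vehicle libraries a median of 89.5% of age-called genes still had ouabain changes of the opposite sign (73.0% to 94.9% over the splits). Unequal depth is argued against in the same way, since with all libraries thinned to the shallowest the median was 88.6% (72.7% to 94.5%). The amount of immune cells stays open, because the median within-group correlation with the immune markers was 0.16 for the genes that rose with age and -0.15 for those that fell, both between the values set for and against it. An effect of ouabain itself remains a candidate explanation, along with any difference in handling that the labels do not give.

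The second pattern is the lower level of male-biased genes in old vehicle livers than in young and in ouabain livers. Male mice among the libraries are argued against by 4 Y-linked genes, whose summed level was at most 0.465 CPM in any library. With the preset correlation, reliance on 1 library is argued against by a largest camera adjusted p of 1.17e-12 over the fits without 1 library. The list did not pass with an estimated correlation, but only the real one of 100 splits of the libraries gave a camera p as small. What stays open is a biological difference in the hormonal state of the mice, as no hormone was measured. The list of growth hormone and IGF axis genes passed in 0 of 18 fits without 1 library for ouabain versus vehicle (camera adjusted p 0.830 to 0.998). It also passed in 0 of 18 for vehicle versus young (0.651 to 0.989). Transcripts of these genes do not measure the hormones themselves, so this does not settle it. Housing or timing differences that follow the groups stay open as well. Circadian clock genes as a list were higher with ouabain than with vehicle in 17 of 18 fits without 1 library (camera adjusted p 0.00514 to 0.105). For that list 28 of 100 splits gave a camera p as small, so it does not settle timing.

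The third pattern is the lower level of macrophage and inflammatory genes with ouabain. Chance in the assignment of libraries stays open for the macrophage list: 6 of 100 splits, the real one included, gave a camera p as small. The list did not pass with an estimated correlation. With the preset correlation, reliance on 1 library is argued against for the monocyte-derived macrophage list (largest adjusted p of 4.34e-07 when each was left out). It holds for other lists, as Kupffer cell markers reached 0.315 without old vehicle replicate 4 and MHC class I genes 0.291 without old vehicle replicate 3, and Ccr2, Ms4a7 and Ms4a6c passed in 9, 12 and 11 of 18 such fits. A larger share of hepatocytes is argued against only as the whole reason. Endothelial and stellate markers had a median change of 0.0152 and the macrophage markers an upper quartile of -0.63. Bile duct markers belonged to the same expectation but were left out of the value tested. Bile duct markers (median -0.41) and hepatocyte secretory genes (0.04) moved as a larger share needs. Each had a camera adjusted p of 0.049 and passed in 5 of 18 fits without 1 library. Their adjusted p rose to 0.222 without old vehicle replicate 5 and 0.209 without old vehicle replicate 6, respectively. Neither passed with an estimated correlation (0.534 and 0.563). A part played by the hepatocyte share is thus not excluded, and the amount of immune cells was not tested for this pattern. Residual blood cannot be told apart: 8 erythroid genes had a median change of -0.42, less than the macrophage markers (-0.91), but haemoglobin genes followed the macrophage markers within groups with a correlation of 0.60.

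Chance in the assignment of libraries is argued against for the counts of genes. In 100 splits of the 12 libraries each, the real one included, only 1 split (the real one) reached 262 genes for ouabain versus vehicle (highest other 45), 2733 for vehicle versus young (740) and 160 for ouabain versus young (0). For the 231 opposite calls, only 1 of 100 splits of the old libraries (highest other 0) and 1 of 100 of the vehicle and young libraries (highest other 4) gave as many, but most of these splits called few genes at all. With ouabain and young libraries regrouped, 85 of 100 splits gave at least 231 (median of the others 344, highest 542). That regrouping puts young livers in the ouabain group, so the count does not test chance there. The count shows that vehicle livers stood apart from the other 2 groups, not which of these lay nearer to them. Ouabain livers differed from vehicle livers in fewer genes (262) than young livers did (2733), and from young livers in 160. These counts depended on single libraries and are not distances. For gene lists chance in the assignment cannot be excluded. As many as the 22 lists of ouabain versus vehicle came from 15 of 100 splits (highest other 28). As many as the 22 of vehicle versus young came from 23 of 100 (highest other 29). Only 1 of 100 gave the 23 of ouabain versus young (highest other 22). Camera with a preset correlation called a median of 17 lists in the other splits of ouabain and vehicle libraries, whereas fry called at most 2 against 4 in the real one.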

How the results depend on the processing

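The dropping of both doubted libraries (old vehicle replicate 4 and old ouabain replicate 5) and the thinning were chosen after seeing the data. Where a value moved, the cause was not tested, except that thinning and dropping leave fewer counts or libraries. The age effect was the steadiest: the 2733 genes of old vehicle versus young stayed within 1.5 times under 11 other settings (1831 to 3209). These include the one without both doubted libraries. With only 3 vehicle libraries the age effect had a median of 1713.5 genes (1104 to 2381). Its count of lists (22) moved by over 1.5 times with an estimated correlation (3), and was 17 to 25 under the other settings. The genes of old ouabain versus old vehicle (262) went to 599 with DESeq2, 1002 with quality weights, 53 with 1 surrogate variable, 85 without both doubted libraries and 133 after thinning. The opposite calls (231) went to 501, 739, 51, 82 and 124 under the same settings, and to 38 with the vehicle libraries split 3 and 3, with 0 genes in the same direction by the median split and under each of the others. The genes of old ouabain versus young (160) went to 466 with DESeq2, 532 with quality weights, 333 in the fit of only these groups, 103 without both doubted libraries and 78 after thinning. Lists of old ouabain versus old vehicle (22) went to 0 with an estimated correlation and 4 by fry, and those of old ouabain versus young (23) to 0 and 7.

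Leaving out 1 library gave 69 to 642 genes for old ouabain versus old vehicle. It moved them by over 1.5 times without ouabain replicates 1 (552), 3 (79), 4 (76), 5 (130) and 6 (69) and vehicle replicates 1 (152), 2 (139), 3 (124), 4 (172) and 6 (642). It gave 51 to 612 for old ouabain versus young, with such moves without ouabain replicates 2 (51) and 5 (77) and young replicates 1 (612), 3 (71), 4 (76), 5 (64) and 6 (96). It gave 2085 to 3061 for old vehicle versus young and 66 to 570 opposite calls, which moved as far without ouabain replicates 1 (409), 3 (74), 4 (71), 5 (118) and 6 (66) and vehicle replicates 1 (139), 2 (126), 3 (113) and 6 (570). Lists ran from 16 to 23, 19 to 25 and 21 to 26 in the same order. The replicate numbers do not pair the libraries: deviations of same-numbered libraries correlated at -0.12 to 0.16 for ouabain and vehicle, and 2 of 6 matched their own number best (1 of 6 and 0 of 6 in the other comparisons). With the replicate block the counts were 241, 2522 and 71 genes and 220 opposite calls.

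Of 37 named genes that passed for ouabain versus vehicle, 17 passed under every setting and every library left out, among them Slco1a1, Nudt7, Cyp2d9, Ces3b, Tnfrsf1b and, of the macrophage markers, Itgax alone. The numbers were 47 of 49 for vehicle versus young and 8 of 27 for ouabain versus young. Among the genes named, 1 near 0 changed sign. Lmnb1 for ouabain versus vehicle went to -0.14 after thinning and ran from -0.062 to 0.0580 when 1 library was left out, negative in 5 such fits. The filter at 1 CPM left 14233 genes, about as many as the main one, and tests little. Depth limits genes of a few counts, such as Cdkn2a and, in vehicle livers, Hsd3b5.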

Other observations

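The use of the splits list by list and the choice of the unnamed genes came after the results were seen. Taken list by list, the same 100 splits separate the ouabain results. Male-biased liver genes were the 1 list of the 22 called for ouabain versus vehicle whose camera p was matched by fewer than 5 splits (only the real one). For monocyte-derived macrophage markers 6 splits and for NF-kB feedback and targets 5 splits gave a p as small, for interferon-stimulated genes 39 and for Kupffer cell markers 54. For old vehicle versus young, 8 of the 22 called lists were matched by fewer than 5 splits. Among them were male-biased genes, MHC class II, macrophage and plasma cell markers, p53 targets and endoplasmic reticulum chaperones. For old ouabain versus young 9 of the 23 called lists were, among them female-biased genes, MHC class II, macrophage and plasma cell markers and endoplasmic reticulum chaperones.

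A group of 37 gene identifiers without a symbol stood apart in old ouabain replicate 3, where each was at 12.6 to 17.2 CPM with a mean of 14.7 CPM. Their mean was 0.354 to 2.36 CPM in every other library. None passed for ouabain versus vehicle (log2 fold changes of 1.30 to 2.19, adjusted p 0.122 to 0.368). What they are was not tested here.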
